A study of Homo sapiens with 6 samples.

How the data were processed

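RNA expression was measured in sections of formalin-fixed, paraffin-embedded (FFPE) human liver. Per the labels, 3 samples came from livers with acute liver failure (ALF), the sudden loss of liver function, and 3 from normal liver, with 1 array each. Per the labels' protocols, total RNA was extracted with a kit made for FFPE tissue and biotin-labelled cRNA was prepared from it. FFPE RNA is fragmented and chemically modified, and array signals from it can lose range.

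The deposited values are log2 expression values per probe set. Per the submitters' processing notes, the authors used the Transcriptome Analysis Console and RMA, a method that corrects background, quantile-normalizes probes and summarises them per probe set. The versions, filters and genome build are not given in the sources used here. The table held 33297 probe sets and came without detection calls, so no gene was declared present or absent. A fold against a level near the bottom of the range is compressed by background. The scanner files were not used here.

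Probe sets were named through the platform's annotation table, dated 2016, with 19460 probe sets assigned to 1 gene symbol, 1754 to several and 12083 to none. The Entrez ID of 19429 single-gene probe sets matched the RefSeq table of assembly GRCh38.p14, used for names and gene types only, and 0 symbols changed. No gene was named from a probe set with several symbols. Each gene was represented by its probe set with the highest mean over the 6 arrays, a choice that concerned the 768 genes with more than 1 probe set. This gave 18393 genes, of which 16888 code for protein. Genes that could show the sex of a donor were left out of every table. Close family members, such as CYP3A4 and CYP3A5, CYP2B6 and its pseudogene CYP2B7P, or the MT1 metallothioneins, can share hybridisation, so their separate values are uncertain.

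ALF was compared with normal liver by linear models with moderated variances (limma 3.58.1 in R 4.3.3; lmFit and eBayes) on the deposited log2 values, with group as the only term and a two-sided test. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes are called higher or lower. Changes are log2 differences, ALF minus normal, with standard errors (SE) from that model. The labels do not say whether the samples came from separate donors, so p-values measure only the spread between these samples. With 3 against 3 arrays, an exact two-sided permutation test cannot give a p below 0.1. The number of arrays limits the precision. On simulated data of the same size, 58.6% of 70 genes changed 2-fold, 100% of 70 changed 4-fold and 100% of 60 changed 8-fold were recovered. There, 10 unchanged genes were called. The changed genes were picked at random, with independent noise of equal size in both groups, so this recovery need not hold for real changes. In the real data, 37 of 48 genes at least 4-fold higher and 118 of 241 at least 4-fold lower were called.

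Before the data were examined, 35 gene lists were fixed, covering hepatocyte functions, lobular zones, injury and inflammation, regeneration, other cell types, an off-tissue control and technical controls. They hold 885 genes, of which 785 were measured; the others were not analysed here. Lists were tested with limma camera at a preset inter-gene correlation of 0.01, which compares a list's genes with all other genes, adjusted over the 35 lists. The alternatives were camera with an estimated correlation and fry, which tests whether a list's genes move, on balance, one way. In the simulation, a list of 25 genes moved by a log2 change of 1 had an adjusted p of 5.16e-39 and 0 of 100 unchanged lists were called. That simulation had no coordinated differences between arrays. For each list the count of called members is also given with p adjusted over the list alone.

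The genes to name were set by a rule fixed at the same time: the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, leaving out uncharacterised loci and small RNA symbols; the 2 called members of each list with the largest change, or for a list with none the member with the smallest p; and ALB, AFP, KRT7, KRT19, HGF and MKI67. The alternatives covered 3 further normalizations, filters on dim genes, other uses of probe sets, other variance models and thresholds, the replicate number as a block, and leaving out each array. An equal spread of values on every array and a restriction to protein-coding genes were added after seeing the data. GC content and probe length were not examined, since no sequence was used. Figures were drawn with matplotlib.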

Results

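Whole-transcriptome arrays measured RNA in FFPE liver from 3 samples with ALF and 3 of normal liver, to compare the failing organ with the normal one. The 6 arrays had nearly equal medians, between 4.58 and 4.62 on the log2 scale. The SD of gene values was 1.51, 1.40 and 1.32 on the arrays of ALF 1, 2 and 3, and 1.60, 1.49 and 1.57 on those of normal 1, 2 and 3. No 2 arrays held the same values, with correlations across genes of 0.925 to 0.950 within ALF and 0.959 to 0.976 within normal liver. The first principal component held 59.7% of the variance and separated the groups, with ALF 2 farthest from normal liver and normal 2 nearest to ALF.

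Livers with ALF had lower expression of many genes that hepatocytes use for secretion, detoxification and metabolism, and higher expression of many genes of cell division and collagen matrix. CYP3A4, the main drug-metabolising cytochrome P450 of the liver, fell from 10.43 ± 0.75 in normal liver to 3.23 ± 0.46 in ALF (log2 expression, mean ± SD, n = 3 each). This was a log2 change of -7.20 (SE 0.38, adjusted p = 0.00139, limma), or 147-fold. SPP1, which encodes the secreted phosphoprotein osteopontin, rose from 5.85 ± 0.38 to 10.58 ± 1.00, a log2 change of 4.73 (SE 0.46, adjusted p = 0.00854, limma), or 26.6-fold. AKR1B10, an aldo-keto reductase, rose by 4.60 (SE 0.83).

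The other largest rises under the naming rule were in MMP7 (3.07), a matrix metalloproteinase of ductular cells, BIRC5 (3.03), which encodes the mitotic protein survivin, CD24 (2.97), PTTG1 (2.91), which encodes securin, PCLAF (2.78), a PCNA-binding factor, and TOP2A (2.68), the topoisomerase of dividing cells. BIRC5 and PCLAF each had 2 probe sets. Their lowest changes over all alternatives were 0.69 and 1.77, against 2.70 and 2.67 when 1 array was left out. The other largest falls were in HSD17B13 (-5.28), a lipid droplet enzyme of hepatocytes, CYP2B6 (-4.60), CYP1A2 (-4.24), HSD17B6 (-4.14), CYP2B7P (-4.06), PON3 (-4.03), which encodes a paraoxonase, and PLA2G2A (-4.01), a secreted phospholipase. CYP2B7P is a pseudogene closely related to CYP2B6, and hybridisation shared between them cannot be separated here.

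**Figure D1:**
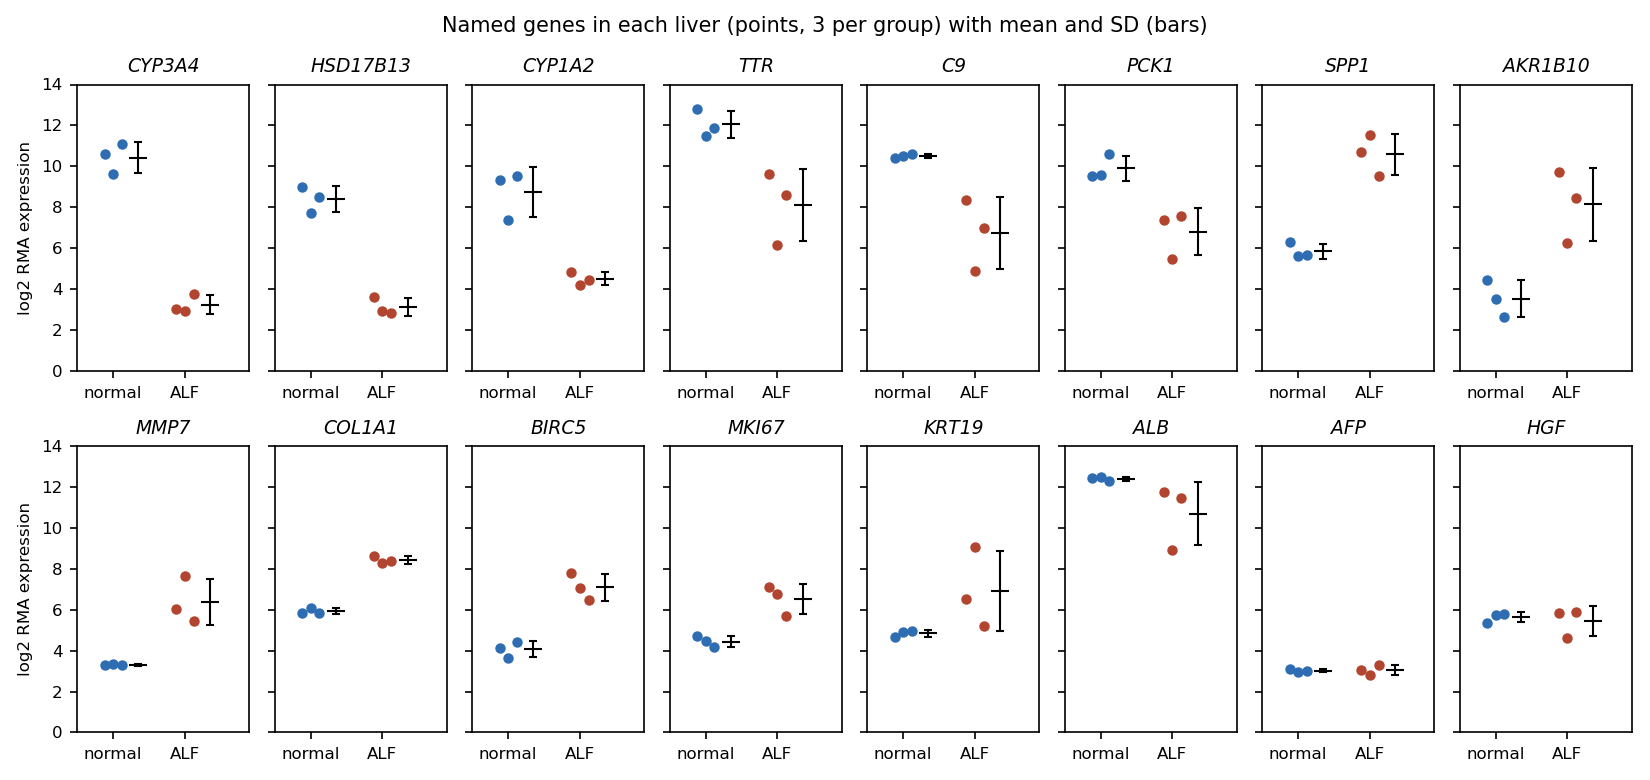
Log2 RMA expression of 16 named genes in each of the 6 livers (points, normal in blue, ALF in red), with the mean and SD of each group of 3 beside them. CYP3A4 lies between 2.92 and 3.76 in ALF and between 9.61 and 11.08 in normal liver, whereas the groups overlap for AFP and HGF.

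In total, 438 of 18393 genes differed between ALF and normal liver at an adjusted p under 0.05 in limma, 172 higher and 266 lower. Higher genes were 39.3% of these, but 49.3% after cyclic loess, 51.9% with an equal spread on every array and 56.3% after quantile normalization (269 higher, 209 lower). The balance also turned with single arrays: 71.7% were higher without ALF 3 (198 higher, 78 lower), against 26.5% without ALF 1 and 25.7% without normal 2. At least 2-fold changes were found in 377 of the 438 genes. Among them, 37 were higher and 118 lower by at least 4-fold, and 5 were higher and 45 lower by at least 8-fold. Groups did not overlap for 21.3% of all genes. The average by chance is 10%, but genes that vary together can move the share of a single split far from it. The number of called genes was 17 without normal 1, 26 without normal 3, 243 without ALF 2, 276 without ALF 3, and 696 without normal 2. Of the 52 named genes past the threshold, 9 passed without normal 1 and 10 without normal 3; COL1A1, COL1A2, GPNMB, CYP3A4, HSD17B13, IGFBP1, PCLAF and SPP1 passed whichever array was left out. AKR1B10, AKR1D1, HSD17B6, LUM, NNMT, SLC10A1 and TPM2 passed in 1 of those 6 fits, and CLEC4M and HBD in 0. After quantile normalization 16 of the 52 lost their call, after cyclic loess 13 and with an equal spread 12. The latter 12, lost in all of these settings, were ACSM5, C9, CYP2B6, F11, HBB, HBD, HSD17B6, ITIH1, ITIH4, NNMT, PCK1 and TTR.

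Of the 35 gene lists, 7 were shifted up and 16 down in ALF at an adjusted p under 0.05 in limma camera. With an estimated inter-gene correlation 0 lists passed (5 at an unadjusted p under 0.05, and a lowest adjusted p of 0.226). By fry 1 list passed, extracellular matrix (adjusted p = 0.0311), and 18 had an unadjusted p under 0.05. Splits of the 6 arrays that mixed ALF with normal liver gave 4 to 22 lists past the camera threshold; each such split still sets unequal numbers of ALF arrays against each other, so part of the group difference stays in it.

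**Figure D2:**
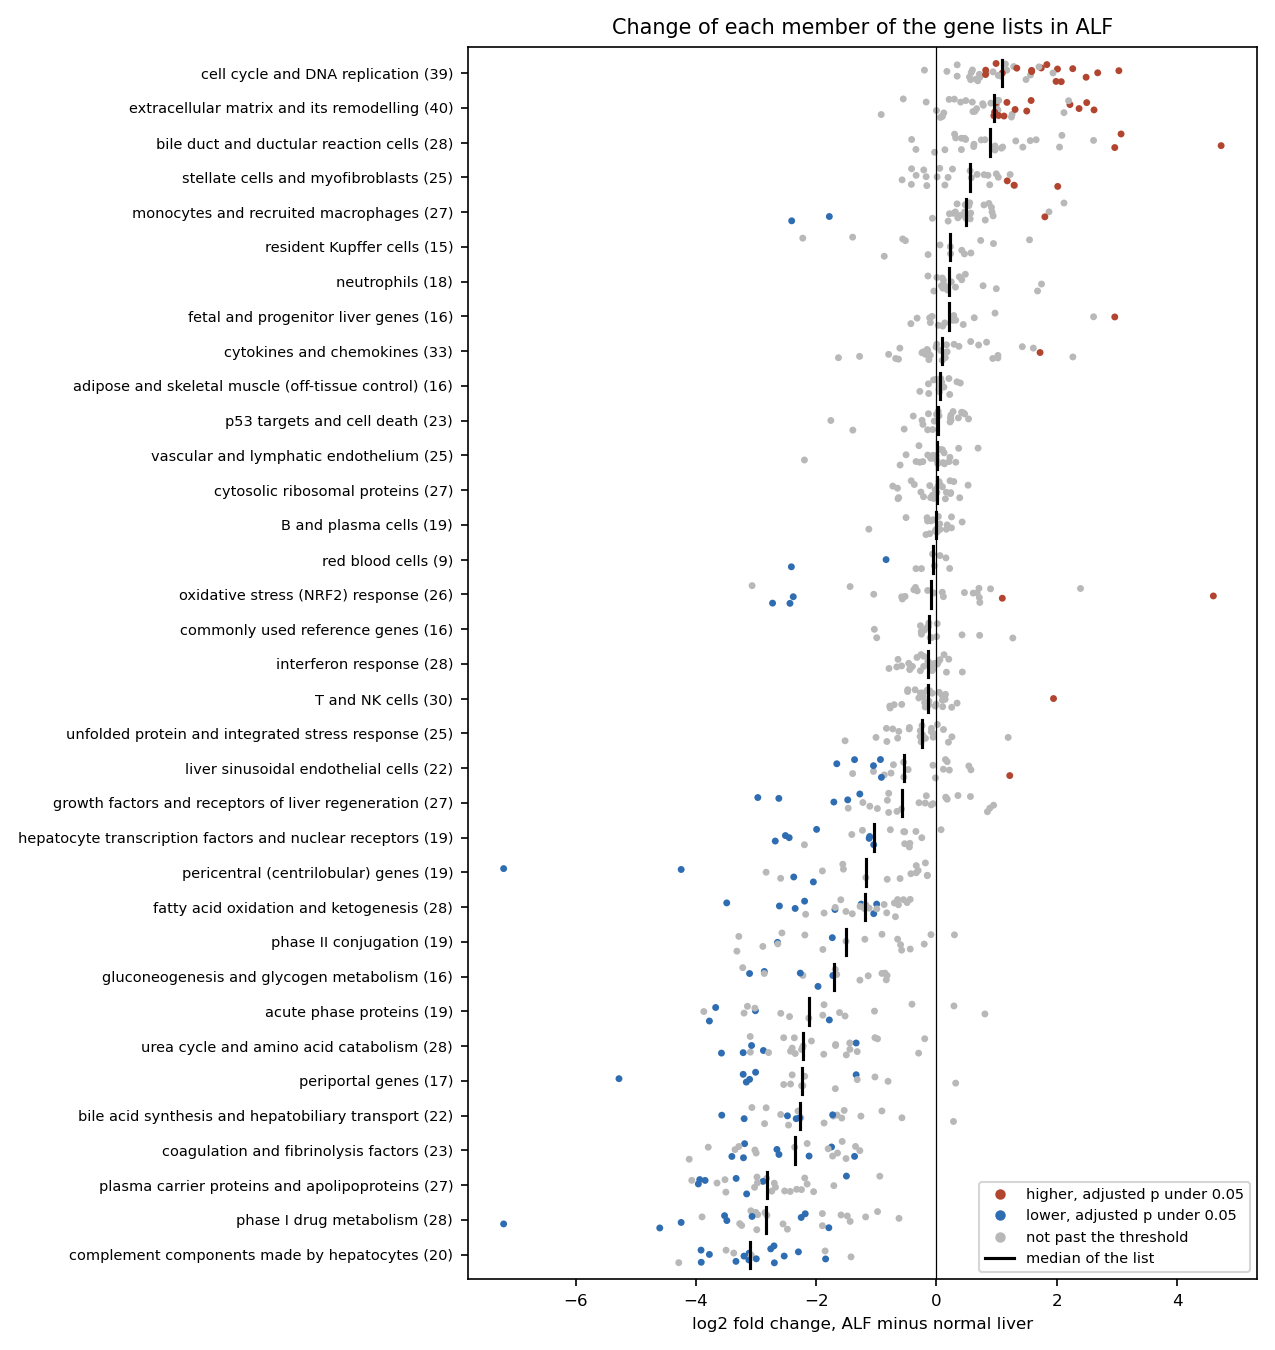
Log2 fold change, ALF minus normal, of each measured member of the 35 gene lists (points, red higher and blue lower at an adjusted p under 0.05, grey not past it; number measured in brackets), with the list median as a black bar. Medians run from -3.10 for complement components to 1.10 for cell cycle genes; the medians of ribosomal protein and reference genes, near 0 here, are 0.63 and 0.38 after quantile normalization.

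Many genes for hepatocyte function fell: 57 of the 210 measured members of 9 lists were lower, 0 were higher, and 207 had a change below 0. Among plasma carrier proteins and apolipoproteins, 7 of 27 members fell (27 adjusted over the list alone), with a median log2 change of -2.82. ITIH1 fell by 3.96, and TTR, which encodes the thyroxine and retinol carrier transthyretin, fell by 3.93 from a normal level of 12.04 ± 0.68 (n = 3). Among coagulation and fibrinolysis factors, 8 of 23 fell (23 adjusted over the list alone), with a median of -2.36. F11 fell by 3.40 and F2, the gene for prothrombin, fell by 3.21. In camera the adjusted p of these lists was 3.71e-20 and 4.34e-20, against an adjusted p = 0.226 with an estimated correlation for both. Called plasma carrier genes numbered 3 after quantile normalization, cyclic loess and an equal spread, 11 without ALF 2, 1 without ALF 3, 1 without normal 1 and 0 without normal 3. Called coagulation genes numbered 2 after quantile normalization, 5 after cyclic loess and an equal spread, 13 without ALF 2, 2 without ALF 3, and 0 without normal 1 or normal 3.

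Among phase I drug metabolism genes, 9 of 28 fell (27 adjusted over the list alone), with a median of -2.83, led by CYP3A4 and CYP2B6. Among phase II conjugation genes, 2 of 19 fell (6 adjusted over the list alone), with a median of -1.50 (-0.64 without ALF 2 and -0.99 after quantile normalization). These were GLYATL1, a glycine conjugating enzyme, at -2.64 (SE 0.40), and NNMT, nicotinamide N-methyltransferase, at -1.73 (SE 0.33). The change of NNMT ran from -2.01 to -0.93 over the alternatives. Among genes of bile acid synthesis and hepatobiliary transport, 6 of 22 fell (19 adjusted over the list alone), with a median of -2.26. AKR1D1, a reductase of bile acid synthesis, fell by 3.57, and SLC10A1, which encodes the bile acid uptake transporter NTCP, fell by 3.20. By camera these lists had an adjusted p of 8.72e-23, 1.52e-07 and 3.45e-14. The adjusted p was 0.226 with an estimated correlation for phase I and bile acid genes, and 0.287 for phase II. Called phase I genes numbered 15 without normal 2. Called bile acid genes numbered 3 without ALF 1 or ALF 2 and 13 without normal 2, and called phase II genes 1 after quantile normalization, cyclic loess or with an equal spread.

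Parts of intermediary metabolism were lower as well. In urea cycle and amino acid catabolism, 5 of 28 members fell (25 adjusted over the list alone), with a median of -2.22 (-1.35 without ALF 2). CTH, which makes cysteine from cystathionine, fell by 3.57 and AGXT, the peroxisomal alanine-glyoxylate aminotransferase, had a log2 change of -3.21. In gluconeogenesis and glycogen metabolism, 5 of 16 fell (13 adjusted over the list alone), with a median of -1.70. PCK1, the rate-controlling enzyme of gluconeogenesis, fell by 3.11 and GYS2, liver glycogen synthase, had a log2 change of -2.86. In fatty acid oxidation and ketogenesis, 8 of 28 fell (24 adjusted over the list alone), with a median of -1.19, led by ACADSB (-3.49) and ACSM5 (-2.61). Among hepatocyte transcription factors and nuclear receptors, 7 of 19 fell (9 adjusted over the list alone), with a median of -1.04 (-0.67 without ALF 2), led by the coactivator PPARGC1A (-2.68) and the carbohydrate-responsive factor MLXIPL (-2.51). These 4 lists had a camera adjusted p of 2.86e-18, 1.59e-13, 6.34e-18 and 7.27e-11, against an adjusted p = 0.226 with an estimated correlation for each. Of the 57 calls among hepatocyte function genes, the count was 2 without normal 1, 1 without normal 3, 13 without ALF 3 and 86 without normal 2. Each of the 9 lists had 0 or 1 called members without normal 1 or normal 3, and 0 to 4 without ALF 3. Without ALF 1 the called members were 3 for urea cycle, 3 for fatty acid oxidation and 4 for transcription factors, and without ALF 2 they were 8, 4 and 3, with 2 for gluconeogenesis. Without normal 2 they were 11 for urea cycle and 9 for gluconeogenesis, and with an equal spread 5 for fatty acid oxidation.

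Genes of both ends of the liver lobule were among the falls. Of 19 pericentral genes, expressed near the central vein, 4 fell (8 adjusted over the list alone), with a median of -1.17 (-0.78 without normal 3), led by CYP3A4 and CYP1A2. Of 17 periportal genes, expressed near the portal tract, 6 fell (15 adjusted over the list alone), with a median of -2.24, led by HSD17B13 and AGXT. The camera adjusted p was 4.54e-10 and 1.06e-13, against an adjusted p = 0.226 with an estimated correlation for both. Of the pericentral and periportal genes, 6 and 13 were also members of other lists. The 10 calls in the zonal lists were 6 without ALF 1, 4 without ALF 3, 2 without normal 1, 2 without normal 3 and 19 without normal 2. Pericentral calls were 2 without ALF 1 and 8 without normal 2, and periportal calls 1 without ALF 3 and 11 without normal 2.

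Complement and acute phase genes, whose products hepatocytes secrete, were among the falls. Of 20 complement components, 14 fell (20 adjusted over the list alone), with a median of -3.10, the lowest of the 35 lists. CFHR4 fell by 3.91 (2 probe sets) and C8B, a component of the membrane attack complex, had a log2 change of -3.91. Of 19 acute phase genes, 4 fell (15 adjusted over the list alone), with a median of -2.12 (-1.38 without ALF 2), led by C9 (-3.77) and ITIH4 (-3.67). The camera adjusted p of the complement list was 2.04e-21 (adjusted p = 0.226 with an estimated correlation) and that of the acute phase list 4.03e-10 (adjusted p = 0.259 with an estimated correlation). Called complement genes numbered 7 after quantile normalization, 11 after cyclic loess and an equal spread, 1 without ALF 3, and 0 without normal 1 or normal 3. Called acute phase genes numbered 1 in each of those 3 settings of scaling, 10 without ALF 1, 1 without normal 2, and 0 without ALF 3, normal 1 or normal 3. Of 33 cytokines and chemokines, only CXCL6, a neutrophil attractant, rose (1.72, SE 0.32), with 6 higher and 2 lower adjusted over the list alone and a list median of 0.10 (0.17 without ALF 2, 0.16 without normal 2 and 0.18 after quantile normalization; camera adjusted p = 0.224). In that list 3 genes were higher without ALF 3, and 0 without ALF 2 or any 1 normal liver.

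Stress responses were mixed. In the oxidative stress list, 2 of 26 members rose and 3 fell (3 and 7 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.646). That median was 0.35 after quantile normalization (3 higher, 1 lower), 0.11 after cyclic loess and 0.20 with an equal spread. It was 0.29 without ALF 2 (3 higher, 0 lower) and -0.38 without ALF 1 (0 higher, 4 lower), and 0.01 and 0.06 without normal 1 and normal 3, where 0 genes were called. Without ALF 3 it had 0 higher and 1 lower, and without normal 2 0 higher and 4 lower (median -0.17). AKR1B10 was the largest rise and the metallothionein MT1G the largest fall, at -2.72 (SE 0.49). No member passed among 25 genes of the unfolded protein response (1 higher and 5 lower adjusted over the list alone), with a median of -0.24 (-0.07 after quantile normalization, -0.12 after cyclic loess and -0.08 with an equal spread). DNAJB9, an endoplasmic reticulum chaperone, had the smallest p there, with a log2 difference of -1.52 (adjusted p = 0.0545, limma). That list had a camera adjusted p of 0.00194, against an adjusted p = 0.331 with an estimated correlation, and did not pass after quantile normalization or cyclic loess, with an equal spread or without ALF 3. Members were called in some settings, 1 higher in each of those 3 scalings, 3 lower without ALF 1 and 1 lower without normal 2. Among 28 interferon response genes 0 passed, also adjusted over the list alone, with a median of -0.13 (-0.24 without ALF 1, -0.23 without normal 2 and -0.01 without normal 3; camera adjusted p = 0.0583). IFITM3 had the smallest p, with a difference of -0.79 (adjusted p = 0.132, limma), which ran from -1.02 to 0.20 over the alternatives. Among 23 p53 target and cell death genes 0 passed (2 lower adjusted over the list alone), with a median of 0.03 (-0.07 to 0.15 when 1 array was left out) and a mean of -0.06 (camera adjusted p = 0.836); 1 was lower without normal 2. GADD45B was nearest to the threshold at -1.39 (adjusted p = 0.0508, limma). Over the injury and inflammation lists the 3 higher and 20 lower genes were 1 and 32 without ALF 1, 3 and 2 without ALF 3, 0 and 19 without normal 2, and 0 and 0 without normal 1 or normal 3. They were 5 and 9 after quantile normalization, and 4 and 15 after cyclic loess or with an equal spread.

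Many cell cycle genes rose in ALF. Of 39 measured genes of cell cycle and DNA replication, 16 rose and 0 fell (31 and 0 adjusted over the list alone), 38 had a change above 0, and the median was 1.10. TOP2A reached 6.10 ± 0.73 in ALF against 3.42 ± 0.22 in normal liver (n = 3 each). BIRC5 was the largest rise by its probe set with the higher mean, but its change was as low as 0.69 in an alternative. MKI67, the proliferation marker Ki-67, rose by 2.08 (SE 0.34, adjusted p = 0.0323, limma). Growth factor and receptor genes of liver regeneration included 5 of 27 that fell and 0 that rose (12 lower and 2 higher adjusted over the list alone), with a median of -0.58 (-0.32 without normal 1). IGF1 fell by 2.97, and IGFBP1, an insulin-like growth factor binding protein, fell by 2.62 (SE 0.18). HGF, the hepatocyte growth factor, had a difference of -0.19 (SE 0.34, adjusted p = 0.865, limma), which ran from -0.41 to 0.24 when 1 array was left out.

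Among 16 fetal and progenitor liver genes only CD24 passed, as a rise (3 adjusted over the list alone), and the list median was 0.21 (0.13 without ALF 1 and also without ALF 2). AFP, the fetal plasma protein, stood at 3.05 ± 0.22 in ALF and 3.02 ± 0.08 in normal liver (adjusted p = 0.959, limma). Both means lay below the array medians of 4.58 to 4.62, where background limits what a change can show. Of the 16 fetal genes, 3 lay above the level of the median gene in normal liver. The camera adjusted p was 3.93e-25 for cell cycle, 0.000137 for growth factors and 0.0313 for fetal genes. With an estimated correlation the adjusted p was 0.226, 0.226 and 0.276. The fetal list did not pass camera after quantile normalization or cyclic loess, with an equal spread or without ALF 3. Over these 3 lists the 17 higher and 5 lower genes were 8 and 3 without ALF 1, 9 and 3 without ALF 2, 19 and 3 without ALF 3, 1 and 1 without normal 1, 17 and 8 without normal 2, and 2 and 1 without normal 3. Cell cycle genes were 8 of the higher ones without ALF 1, 8 without ALF 2, 1 without normal 1 and 2 without normal 3.

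Several matrix and ductular genes rose. Of 40 extracellular matrix genes, 13 rose and 0 fell (25 higher and 1 lower adjusted over the list alone), with a median of 0.96. COL1A2 and COL1A1, the chains of type I collagen, rose by 2.62 (SE 0.19) and 2.50 (SE 0.16), both with an adjusted p of 0.00198 in limma. Of 28 bile duct and ductular reaction genes, 3 rose (10 adjusted over the list alone), with a median of 0.89 (0.50 without ALF 2). These were SPP1, MMP7 and CD24. The number of called ductular genes was 7 without ALF 3, 5 without normal 2, and 1 without ALF 1, normal 1 or normal 3. The duct cell keratins varied widely among ALF livers: KRT19 was 6.93 ± 1.96 against 4.84 ± 0.17 (difference 2.09, adjusted p = 0.238, limma) and KRT7 was 7.28 ± 1.70 against 5.62 ± 0.35 (difference 1.66, adjusted p = 0.294, limma). When 1 array was left out, the difference ran from 1.02 to 2.95 for KRT19 and from 0.72 to 2.38 for KRT7. Of 25 stellate cell and myofibroblast genes, 3 rose (11 adjusted over the list alone), with a median of 0.56 (0.19 without ALF 1 and 0.33 without ALF 3). LUM, the proteoglycan lumican, rose by 2.02 and TPM2, a tropomyosin of contractile cells, by 1.29. Called matrix genes numbered 7 without ALF 1 and 2 without normal 1 or normal 3. Called stellate cell genes numbered 5 after quantile normalization, cyclic loess or with an equal spread, 1 without ALF 2, and 0 without ALF 1, normal 1 or normal 3. The camera adjusted p was 7.38e-16, 2.94e-10 and 0.000185, against an adjusted p = 0.226, 0.248 and 0.300 with an estimated correlation.

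Of 27 genes of monocytes and recruited macrophages, 24 had a change above 0, 1 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.49. After quantile normalization 5 rose and 1 fell (median 0.90), and after cyclic loess and with an equal spread 3 rose and 2 fell (medians 0.72 and 0.81). The calls were 2 higher and 0 lower without ALF 3, and 1 and 0 without normal 1 or normal 3. GPNMB, a glycoprotein of lipid-laden macrophages, rose by 1.80 (SE 0.18), whereas APOE fell by 2.41 (SE 0.40) and CD14 had a log2 change of -1.78; hepatocytes also express APOE. Among 15 markers of resident Kupffer cells 0 passed (2 lower adjusted over the list alone), with a median of 0.23, a mean of -0.03 and an upward camera direction (adjusted p = 0.966). Their median was -0.01 without normal 1, 0.06 without ALF 2, 0.09 without normal 2, 0.42 without ALF 3 and 0.47 without normal 3. Without normal 2, 1 Kupffer marker was lower and 1 neutrophil gene higher. CD5L had the smallest p, with a difference of -2.22 (adjusted p = 0.0630, limma). Among 18 neutrophil genes 0 passed, also adjusted over the list alone, with a median of 0.21 (0.33 without ALF 1 and 0.10 without ALF 2). S100A9 had a difference of 1.75 (adjusted p = 0.176, limma). Of the 18 neutrophil genes, 7 lay above the level of the median gene in normal liver, so background limits what the others can show. The camera adjusted p was 5.46e-06 for monocytes and macrophages and 0.0181 for neutrophils, against an adjusted p = 0.300 and 0.428 with an estimated correlation. The neutrophil list did not pass camera after quantile normalization, with an equal spread, without ALF 2 or without normal 1.

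Of 22 markers of sinusoidal endothelium, 5 fell and 1 rose (11 and 1 adjusted over the list alone), or 2 and 1 after quantile normalization, cyclic loess or with an equal spread, with a median of -0.54 (camera adjusted p = 0.00043, adjusted p = 0.300 with an estimated correlation). DNASE1L3 fell by 1.66 and the lectin CLEC4M fell by 1.36, whereas the fatty acid receptor CD36 was the member that rose (1.22). The 5 lower calls were 3 without normal 2, 1 without ALF 1, and 0 without ALF 2, ALF 3, normal 1 or normal 3. The 1 higher call was 0 without ALF 1, ALF 2, normal 1 or normal 3. Among 25 genes of vascular and lymphatic endothelium 0 passed (1 lower adjusted over the list alone), with a median of 0.00 and a mean of -0.09 (camera adjusted p = 0.681); 1 was lower without ALF 1 or normal 2. PROX1, which hepatocytes also express, had a difference of -2.19 (adjusted p = 0.0549, limma). Of 30 T and NK cell genes, CD52, a surface glycoprotein of leukocytes, rose by 1.95 (SE 0.19), with 1 higher and 2 lower adjusted over the list alone and a median of -0.14 (-0.04 without ALF 1, 0.01 without normal 2 and -0.21 without normal 1, where 0 passed; camera adjusted p = 0.0824). Among 19 B and plasma cell genes 0 passed, also adjusted over the list alone, with a median of 0.00 (camera adjusted p = 0.966). JCHAIN had a difference of -1.12 (adjusted p = 0.220, limma). Few genes of these lists lay above the level of the median gene in normal liver, so background limits what the others can show. They were 9 of 30 for T and NK cells, 6 of 19 for B and plasma cells, and 2 of 9 for red blood cells. Of 9 red blood cell genes 2 fell (2 adjusted over the list alone), HBB with a log2 change of -2.41 and HBD of -0.84, with a list median of -0.06 (0.12 without normal 2 and -0.26 without normal 3; camera adjusted p = 0.0637). Both calls were lost after quantile normalization, cyclic loess and with an equal spread, HBB also lost its call without normal 1 or normal 3, and HBD whichever of the 6 arrays was left out. Over all lists of other cell types the 22 higher and 9 lower genes were 10 and 5 without ALF 1, 15 and 3 without ALF 2, 22 and 1 without ALF 3, 4 and 0 without normal 1, and 5 and 0 without normal 3. They were 29 and 3 after quantile normalization, 27 and 4 after cyclic loess, and 27 and 5 with an equal spread.

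**Figure D3:**
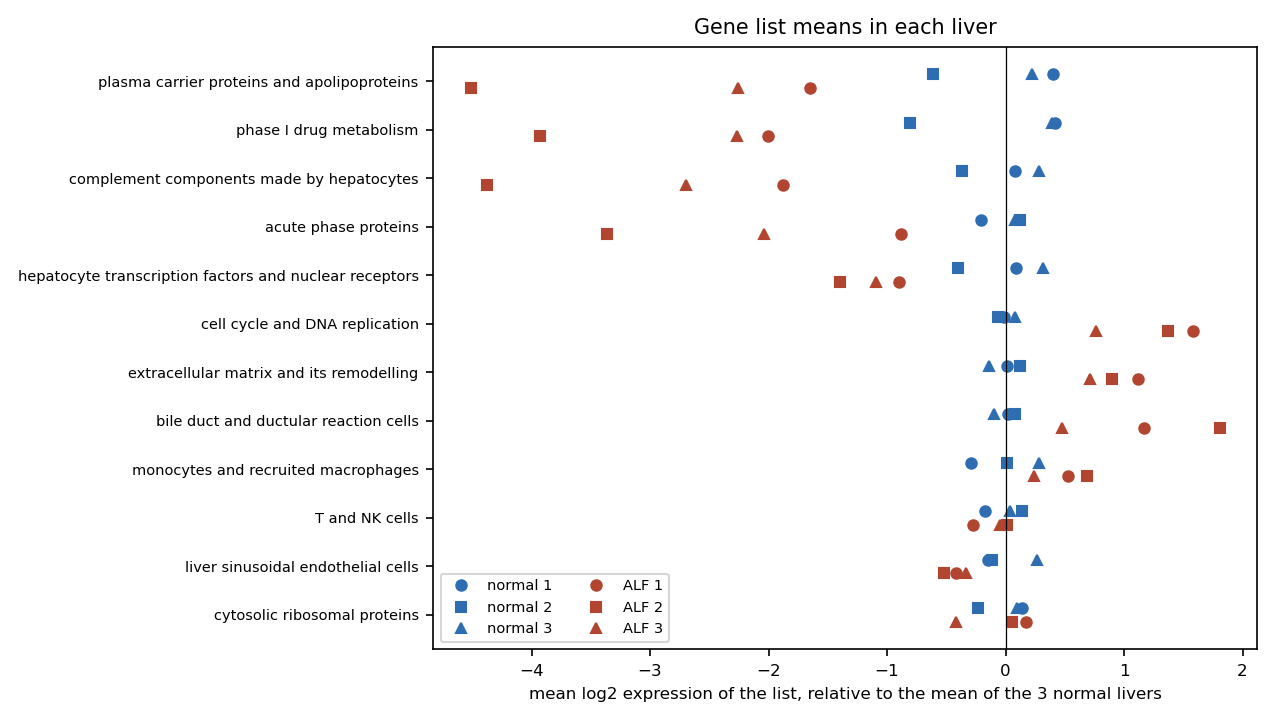
Mean log2 expression of 12 gene lists in each liver, relative to the mean of the 3 normal livers (symbols mark the sample number, blue normal, red ALF). The mean of plasma carrier genes was -4.51 in ALF 2, -2.26 in ALF 3 and -1.65 in ALF 1, against -0.62 in normal 2, 0.22 in normal 3 and 0.40 in normal 1; ribosomal protein means depend on the scaling of the arrays.

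ALB, the gene for albumin and a product of hepatocytes alone in this organ, was 10.70 ± 1.55 in ALF and 12.40 ± 0.09 in normal liver (n = 3 each). Its difference of -1.71 (SE 0.65, adjusted p = 0.227, limma) did not pass the threshold, and ran from -2.22 to -0.81 when 1 array was left out. Of 43 technical control genes 0 were called in limma, but several alternatives called some. After quantile normalization 7 were higher (6 ribosomal, 1 reference). After cyclic loess, with an equal spread, without ALF 3, with either dim-gene filter, with the mean of probe sets and with protein-coding genes only, 1 was higher. With array weights, with the replicate block and at an adjusted p under 0.1, 1 was higher and 2 were lower. The median of 16 adipose and skeletal muscle genes was 0.05 (camera adjusted p = 0.44; 0 adjusted over the list alone), and CIDEC, with the smallest p, differed by 0.40 (adjusted p = 0.245, limma). For 27 cytosolic ribosomal protein genes the median was 0.00 and the mean -0.07 (camera adjusted p = 0.966; 0 adjusted over the list alone), but the median was 0.63 after quantile normalization, 0.38 with an equal spread on every array, 0.30 after cyclic loess, 0.20 without ALF 3 and -0.17 without normal 2. RPL5, with 3 probe sets, had a difference of 0.53 (adjusted p = 0.134, limma). For 16 commonly used reference genes the median was -0.13 (camera adjusted p = 0.443; 1 higher and 2 lower adjusted over the list alone), and 0.38 after quantile normalization, 0.14 after cyclic loess, 0.19 with an equal spread and 0.08 without ALF 3. TUBA1B had the smallest p among them, with a difference of 1.27 (adjusted p = 0.0508, limma).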

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

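An equal spread of values on every array and a restriction to protein-coding genes were chosen after seeing the data. All 438 called genes that an alternative tested kept their direction in it, and the 52 named ones past the threshold kept 1 sign in every alternative. Several alternatives, such as the dim-gene filters, the thresholds and the unequal-variance test, reuse the log2 changes of the main fit, so no direction could turn there. The groups of the 52 named called genes did not overlap, so leaving out 1 array could not turn their sign either. Total counts stayed within 1.5 times of 438 for the normalizations (408 to 478), the dim-gene filters (454 and 415), the mean of probe sets (446), protein-coding genes (417), trended robust variances (516) and a 2-fold minimum (377). Higher genes numbered 269 after quantile normalization and 113 without genes below the median level. Testing every non-control probe set called 244 (110 higher, 134 lower), with more tests adjusted together. Array weights gave 1169 (464 higher, 705 lower), an adjusted p under 0.1 gave 1129 (460, 669), and 2-fold with an unadjusted p under 0.05 gave 1055 (315, 740). An unmoderated unequal-variance test called 0 genes, 0 higher and 0 lower, with 1770 at an unadjusted p under 0.05 against 3166 in limma. Leaving out 1 array gave 17 to 696 genes, 8 to 198 higher and 9 to 517 lower. The count was 17 without normal 1 and 26 without normal 3, but 696 without normal 2. These fits had equally many arrays, so the smaller number of arrays alone does not give this range. Normal 2 lay nearest to ALF on the first principal component (17.3, against 49.4 for normal 1 and 43.9 for normal 3). The cause of the range was not tested. Deviations from the group means of same-numbered samples correlated by 0.293, 0.283 and -0.002. Those of differently numbered samples of the other group correlated by -0.328 to 0.106. Whether the numbers pair the samples cannot be told from these values. The replicate block gave 1137 genes (354 higher, 783 lower) and 23 lists. Of the lists, 23 to 25 passed camera in the normalization, filter, block and leave-one-out settings, and the 23 kept their direction. Of these 23, 20 remained past after quantile normalization and with equal spread, 21 after cyclic loess and without ALF 3, and 22 without ALF 2 or normal 1; those lost were among the fetal, neutrophil and unfolded protein lists. With an estimated correlation 0 passed (0 up, 0 down), and by fry 1 (1 up, 0 down). Lists not past the threshold that moved past it with the other sign were the reference genes after quantile normalization (0.38) and the ribosomal proteins after quantile normalization (0.63), cyclic loess (0.30) and equal spread (0.38); sign changes of lists past it in no setting were not counted. The cause was not tested. Background limits the folds of dim genes, and no detection calls came with the values.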

Other observations

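The tests of explanations in this part were chosen after the results were seen, except the 2 comparisons with other splits of the arrays. Several genes outside the lists, named here after their values were seen, were past the threshold in limma. Their calls were not followed singly through the alternatives, where all calls together numbered 17 without normal 1 and 26 without normal 3. The glycolytic enzyme gene PKM rose by 2.09 (SE 0.38) and LDHB, a lactate dehydrogenase subunit, by 1.89 (SE 0.23). The myeloid genes MNDA, GPR34 and PLA2G7 rose by 2.25, 2.13 and 1.82, and FAP, a protease of activated fibroblasts, by 1.79 (SE 0.25). ECT2 (2.46), ANLN (2.34) and NCAPG (2.30), which act in mitosis or cytokinesis, rose with the listed cell cycle genes. The sterol synthesis genes MSMO1 and SC5D had log2 changes of -2.47 and -2.28, the lipid droplet gene PNPLA3 of -1.79 (SE 0.17), and CHI3L1, a secreted chitinase-like protein, of -3.22 (SE 0.30).

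Small RNAs were left out of the naming rule but held the third largest rise among called genes, in the small nucleolar RNA SNORD78 (3.41, SE 0.48). Of 198 small nuclear, small nucleolar and vault RNA genes, 11 were higher and 1 was lower, SNORD94 (-1.26), and 153 had a change above 0. The vault RNAs VTRNA1-1 and VTRNA1-3 rose by 2.42 and 1.84, and RNU5E-1 by 2.71. The calls of these single small RNAs were not followed through the alternatives either. Among probe sets assigned to several genes, 0 of 1754 passed in limma (285 at an unadjusted p under 0.05), and among those with no gene name 0 of 7880 (770 at an unadjusted p under 0.05).

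The fall of hepatocyte genes had a median log2 change of -2.10 over 210 genes. A lower share of hepatocytes alone, with all other cells unchanged in proportions and expression, would make markers of those cells rise alike. Among members above the level of the median gene in normal liver, they did not rise alike. There, 30 matrix genes moved by 1.01 more than 15 vascular endothelium genes (SE 0.149, exact permutation p = 0.1, the smallest that 3 against 3 allow). The 20 sinusoidal endothelium genes moved by -0.47 (SE 0.159). The matrix and vascular lists were compared after their changes were seen. Expression inside the other cells could also part the lists. The values argue only against that strict form, and do not decide whether a lower share of hepatocytes caused the fall. A narrower spread of values on the ALF arrays is argued against as the whole cause by the median of -1.75 that was left with an equal spread, where 41 genes in place of 57 were called lower. Fewer hepatocytes together with shifts in the proportions of the other cell types stay open as untested. So do a mixture of fewer hepatocytes with changes inside the remaining cells, and differences in tissue age or fixation between the groups. The labels give no way to separate them.

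The small RNA rise had a median of 0.37. Dim genes lifted on the ALF arrays would give random lists of like mean level a similar median, but the central 95% of 10000 such lists ended at 0.06, which argues against it. An excess of short RNA in the ALF extracts would also lift microRNA genes. The 28 above the level of the median gene had a median of 0.044 (bootstrap 95% interval -0.02 to 0.13). This does not decide it, because the interval reaches past the limit set for arguing against such an excess. MicroRNA hairpin precursors can also be scarce. RNA from fixed tissue, its yield and the disease cannot be told apart here for these genes.

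The rise of cell cycle genes had a median of 1.10, and the central 95% of random lists of like level ended at 0.12. That level was the mean over all 6 arrays, so the rise itself entered the matching. With an equal spread on every array the median of the cell cycle genes was 1.04. These values argue against lifted dim genes as the whole cause. The means of the list relative to normal liver were 1.58, 1.37 and 0.77 in ALF 1, 2 and 3. Which cells divide, hepatocytes, duct cells or others, is not given by these values, and a hypothesis of regenerative division in ALF remains untested. A zone-weighted loss with a larger fall of pericentral genes was a further hypothesis, examined after the changes of both lists were known. The values lay the other way. The pericentral minus periportal mean was 0.59 higher in ALF (SE 0.246, exact permutation p = 0.1, the smallest that 3 against 3 allow). It was -1.79, -0.95 and -1.47 in ALF 1, 2 and 3, against -2.05, -2.01 and -1.92 in normal 1, 2 and 3. The pericentral genes had a median normal level of 5.72 against 8.39 for the periportal genes, so a floor on dim genes could have reduced their fall. The comparison therefore does not decide about a zone-weighted loss.

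Chance in the grouping of the arrays cannot be judged by splits, since 3 against 3 arrays make 10 splits and a share under 0.05 is out of reach. The real split called 438 genes and the highest other 0, so 1 of 10 splits gave as many. For lists the real split gave 23 and the highest other 22, again 1 of 10. Each other split sets unequal numbers of ALF arrays against each other, so part of the group difference stays in it and its list count does not show what differences within a group alone would give.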
